A study of Mus musculus with 6 samples.

How the data were processed

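Total RNA, by the labels of C2C12 myoblasts and myotubes, had been hybridised to 6 HG-U133A arrays, 3 per group. Groups and replicate numbers came from the labels. The title of myoblast array 3 does not name the cell stage, so its group came from its description. The numbering in that description covers only the first 2 myoblast arrays, so by the labels alone the group of this array is less certain. Its run record did not name it a myotube. It shared its chip lot with myoblast array 2, with which it correlated at Pearson's r = 0.988. The deposited values are an intensity, 1 signal per probe set on a linear scale, which the authors made with MAS5, per the submitters' processing notes; the version is not given in the sources used here. On each array the values between the 2 percent tails averaged about the same (1499.7 to 1499.8), as global scaling gives. No detection calls were used. The array run records, deposited as text, gave chip type, chip lot, scan day and laboratory code; the numbers in 3 of them, all myoblast, differed from the titles, and the titles were used. Depth has no counterpart here. The highest signal of an unspiked control probe set, between 251.5 and 1040.2 per array, is the level below which a value was not told from background.

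Of 22283 probe sets, 68 were controls and were left out. One result from the controls is not reported here. The platform annotation of 2016 gave 19065 of the others 1 symbol, 1043 several and 2107 none; 54 of them, sex-linked, were then left out, and no gene was named from a probe set with several. A gene was represented by its brightest probe set. Values were taken as log2(signal + 197), where 197 is the 25th percentile of the table, so fold changes understate the change of dim genes. Probe sets with a mean below the 40th percentile were left out. Groups were compared with limma 3.58.1 (lmFit and eBayes with trend, two-sided, R 4.3.3, statmod 1.5.0), with Benjamini-Hochberg adjustment and a threshold of 0.05, and ± after a log2 change is its SE. Before the data were examined, 29 gene lists with 721 symbols were fixed; 610 symbols matched the array. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. Named genes were every measured myogenic regulator, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, and for each list up to 3 called members per direction, or where none was called up to 2 with the smallest p. For 2 genes probe sets were called in both directions. For some named genes, BTG1, HES1, IGFBP3 and TUBB3 among them, 1 of 2 tested probe sets was called. Figures were drawn with matplotlib 3.10.9.

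On simulated data with 13297 probe sets, 37 of 200 probe sets changed by 1 on the log2 scale were recovered with 2 false calls, and 191 of 200 changed by 2 with 11 false calls. The simulated noise was independent between probe sets and arrays, so these counts do not cover errors from structure among the real arrays. Alternatives fixed before the data were examined were the pseudocount, the filter, quantile and 75th percentile scaling, eBayes without trend or robust, the replicate number as a block, chip lot as a random block, the mean of a gene's probe sets, a 2-fold minimum, and leaving out each array. Added after seeing the data were the laboratory series as a block, its first series alone, and myoblast arrays 2 and 3 averaged as 1 sample. The spike-in signal as a covariate and leaving out probe sets above 40000 were also added then. In the first series alone the lone myoblast array is assumed to vary like the myotube arrays. With the block the error also pools the spread between myoblast arrays 2 and 3, which correlated at 0.988. If these 2 are technical repeats, p-values with the block may be too small.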

Results

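RNA that the labels assign to C2C12, a mouse muscle cell line whose dividing myoblasts fuse into multinucleated myotubes, was labelled with biotin and hybridised to short-oligonucleotide arrays, with 3 arrays of myoblasts and 3 of myotubes. The arrays were HG-U133A, designed against human transcripts, while the labels give the organism as mouse, and the species of the RNA was not settled here. Gene names below are those of the human genes the probe sets were designed for. No genome was used here, so no positions are given. Each array gave 1 deposited signal for each of 22283 probe sets, and the number of arrays limits the precision. The labels do not say whether the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

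The arrays differed in the signal of the spike-in controls. Its geometric mean was 48119, 3539 and 4275 on myoblast arrays 1, 2 and 3, and 71439, 33504 and 12320 on myotube arrays 1, 2 and 3. Since all arrays were scaled to about the same mean, this is a level relative to the sample's signal. A low value does not mean weak hybridisation. Myoblast arrays 2 and 3 correlated at Pearson's r = 0.988 across probe sets, while the other pairs within a group lay between 0.875 and 0.894. Myoblast array 1 correlated with myotube array 3 at 0.884, as closely as with myoblast array 3. These correlations are across probe sets, which are not independent replicates. The run records put all myotube arrays on one scan day and all myoblast arrays on another. All myotube arrays also shared a chip lot that held no myoblast array. Neither scan day nor chip lot can therefore be told apart from group. Runs of consecutive laboratory codes were taken as series, a grouping that the records do not name. Myoblast array 1 shared its scan day with the other myoblast arrays and its chip lot with no array. By its code it belonged to the same series as the 3 myotube arrays, and the other 2 myoblast arrays formed a second series. A fit with this series as a block therefore rests on myoblast array 1 against the 3 myotube arrays.

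**Figure D1:**
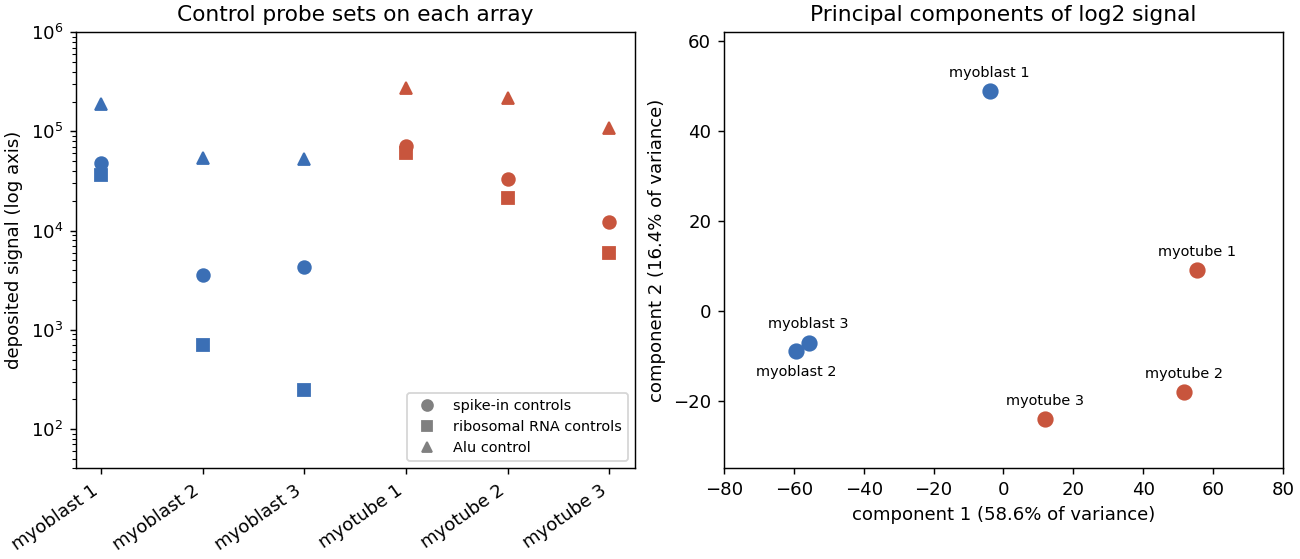
Left, deposited signal (log axis) of the spike-in, ribosomal RNA and Alu control probe sets on each of the 6 arrays; right, the first and second principal components of the log2 signals, with 58.6% and 16.4% of the variance. Myoblast arrays 2 and 3 have the lowest spike-in signals, 3539 and 4275, and lie together at the low end of the first component.

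The comparison of myotubes with myoblasts asks which transcripts change as the cells leave the cycle and differentiate. The 10 largest rises were those of MYL11 (fast skeletal regulatory light chain), C1S (a complement protease), MFAP4, TNNI1 and TNNC1 (slow troponins), GPNMB, MYH3 (embryonic myosin heavy chain), the chemokine CCL2, AKR1C3 and CYP1B1. They ranged from 22.2-fold for MYL11 (log2 4.47 ± 0.72 SE) to 10.2-fold for CYP1B1 (3.36 ± 0.40). The 10 largest falls were those of ID3 and ID1 (inhibitors of myogenic helix-loop-helix factors), PRC1 and CDC20 (mitosis), HMGB2, ARHGDIB, the metallothionein MT1F, RRM2 (ribonucleotide reductase), PBK and CEP55. They ranged from 16.5-fold for ID3 (log2 -4.04 ± 0.32) to 7.03-fold for CEP55 (-2.81 ± 0.36). All 20 had limma adjusted p-values of 0.00438 or less. In 13 of the 20, C1S, TNNI1, TNNC1, MYH3, CCL2, AKR1C3, ID3, PRC1, CDC20, HMGB2, ARHGDIB, PBK and CEP55, each signal of the dimmer group lay at or below the highest unspiked control of its array, so these folds and their order depend on the pseudocount. The same was true of the called genes TNNT1, MYBPH, CASQ2, MAD2L1, NASP, LMNB1, IFIT1 and MGP, and of MYMX, which was not called. For 20 more of the called genes picked by the naming rule, among them MYL11, MFAP4, MYL1, FABP3, ENO3, SNTB1, CHRNE, MEF2C, MCM2, MCM5, HES1, NOTCH3, KLF4, LUM, COL11A1, MX1, CNN1, ADAM12 and VCAM1, it held on 1 or 2 arrays. As a bound chosen after the data were seen, with dimmer signals raised to that control where they lay below it, folds were at least 7.50 for ID3, 2.73 for CEP55, 14.3 for MYL11, 14.7 for C1S, 14.7 for MFAP4, 6.36 for CCL2 and 4.65 for AKR1C3. The order of MYL11, C1S and MFAP4 is thus open. The order of the 20 also depends on myoblast arrays 2 and 3. With the laboratory series as a block the log2 changes were 2.25 for MYL11, 2.21 for CYP1B1, 2.51 for MYH3 and 2.19 for CCL2, and the largest was 4.38 for MFAP4. All 20 were still called.

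Of 13297 probe sets tested, 1478 passed the threshold, 645 higher and 833 lower in myotubes. At the gene level 1042 of 8141 genes passed, 483 higher and 559 lower, and 708 of these changed at least 2-fold. For 1034 of the 1042 the 3 values of one group all lay above the 3 of the other, as they did for 34.6% of all tested genes, where chance gives 10%. The change also varied with brightness over all tested genes. Its median was 0.349 in the dimmest bin of genes and -0.164 between 75 and 95 percent of the brightness ranks. After quantile normalization these medians were 0.102 and -0.048. The list medians below were not corrected for this trend unless quantile normalization is named. The gene count was 2304 without myoblast array 1, 393 without myoblast array 2, 395 without myoblast array 3, 494 without myotube array 1 and 416 without myotube array 2; for probe sets these settings ranged from 488 to 3454. With the laboratory series as a block it was 263 (150 higher, 113 lower), 222 of them called in the same direction without the block, and within the first series alone it was 136. With chip lot as a random block it was 317, but no lot held both groups, so this fit cannot separate lot from group. Of the 89 called genes picked by the naming rule, 44 were called with the series block. Of the other 45, 30 had changes there that were not smaller by more than 1.5 times, and 15 shrank by more than that.

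**Figure D2:**
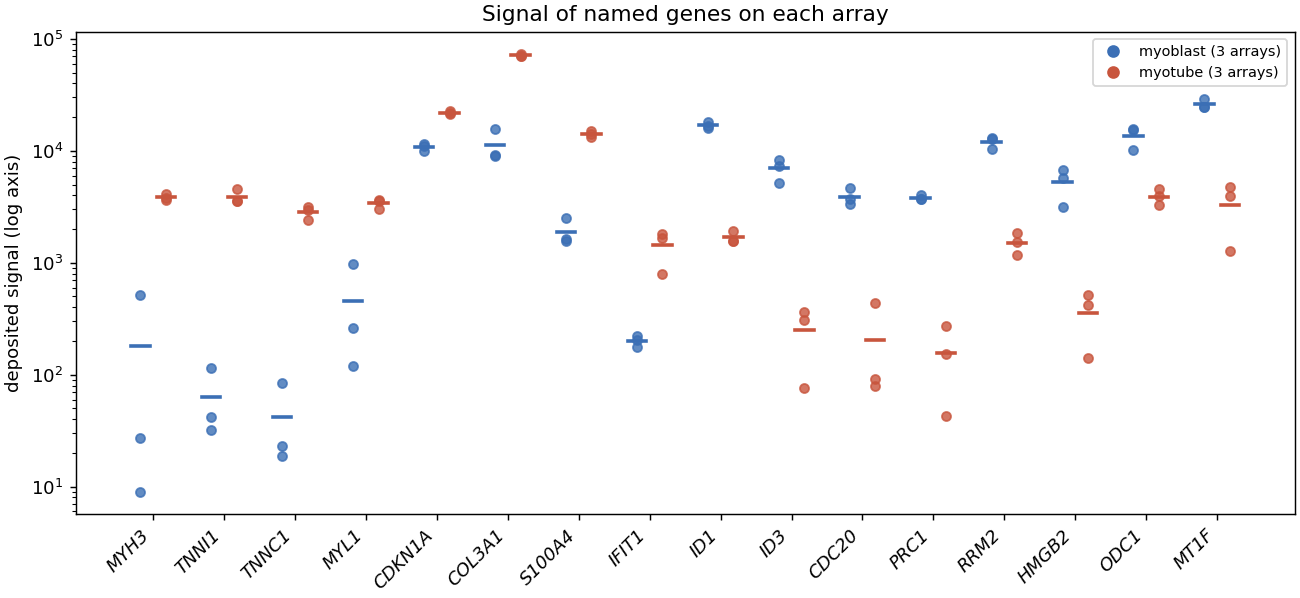
Deposited signal (log axis) of 16 named genes on each of the 6 arrays; points are arrays and bars are means of 3. MYH3 and TNNI1 had mean signals of 3839 and 3895 in myotubes, and ID1 fell from a mean of 17030 to 1688.

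Of the 29 lists, thick filament genes had the highest median change with all arrays and no block, but not in every setting. Over the other settings their median ranged from 0.85 to 2.54, while that of fibroblast markers was never below 1.13. Of 8 measured thick filament genes 4 rose and 4 did not pass, with a median log2 change of 1.86 (limma camera adjusted p = 5.92e-05, and adjusted p = 0.175 with an estimated correlation). MYH3 went from a signal of 182 ± 284 to 3839 ± 225 (SD, n = 3), MYL1 rose 6.49-fold and MYBPH 6.27-fold. Of 19 thin filament and Z disc genes 11 rose and 8 did not pass (median 1.59, adjusted p = 5.25e-09, and adjusted p = 0.187 with an estimated correlation). TNNI1 went from 63.1 ± 45.6 to 3895 ± 545, TNNC1 from 42.3 ± 37.0 to 2848 ± 404, and TNNT1 rose 6.41-fold. Myoblast signals of MYH3, TNNI1, TNNC1, TNNT1 and MYBPH lay among those of unspiked control probe sets, whose highest value per array was between 252 and 1040, so these folds depend on the pseudocount. Adjusted over the list alone, 6 thick and 13 thin filament genes rose. With the series as a block 4 and 6 genes rose, the medians were 1.62 and 1.12, and both lists were called (adjusted p = 8.4e-06 and 3.53e-08), though not with an estimated correlation (adjusted p = 0.0687 and 0.0589).

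Of 12 dystrophin complex and membrane genes 1 rose, the syntrophin SNTB1 (log2 1.40 ± 0.32), and the list was called higher (median 0.65, camera adjusted p = 0.0157, and adjusted p = 0.388 with an estimated correlation); with the series as a block it was not (0.27, adjusted p = 0.225). In muscle energy metabolism 3 of 13 genes rose, and the list was not called (camera adjusted p = 0.248). Among the 3 were the fatty acid binding protein FABP3 (2.12 ± 0.26) and the muscle enolase ENO3 (1.63 ± 0.41, at least 1.74-fold by the bound above). Of 5 acetylcholine receptor and synapse genes 1 rose, CHRNE (1.20 ± 0.31), with no call for the list (adjusted p = 0.0915, and 0.0446 with the mean of a gene's probe sets). In calcium handling CASQ2 (calsequestrin, also in the thin filament list) rose by 2.15 ± 0.33, while the calcium pump ATP2A2 (1 of 3 tested probe sets called) and FKBP1A fell by 1.30 ± 0.24 and 0.93 ± 0.26. That list was not called (adjusted p = 0.973), and its median of 0.01 and mean of 0.23 were positive where the test's direction was lower. Adjusted over the list alone, 2, 4, 1 and 2 genes rose in the dystrophin, energy, receptor and calcium lists, and 0, 1, 0 and 2 fell. Calls of SNTB1, ENO3, CHRNE, ATP2A2 and FKBP1A were lost when one of 3, 3, 4, 2 and 5 arrays was left out, myotube array 1 or 2 among them, with limma adjusted p-values up to 0.0867, 0.0744, 0.151, 0.0598 and 0.147. The series block ended the calls of SNTB1, CHRNE, CASQ2, ATP2A2 and FKBP1A (log2 1.46, 1.12, 1.91, -0.94 and -0.32, adjusted p = 0.112, 0.191, 0.0515, 0.148 and 0.488), of which FKBP1A shrank by more than 1.5 times.

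Of 10 measured myogenic regulators 3 rose and 7 did not pass, and the list was not called (camera adjusted p = 0.248), though it was called higher without myoblast array 2 or 3 (adjusted p = 0.0298 and 0.0374), with both averaged (0.0349) and in the first series alone (0.0151). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose 2.00-fold from 10830 ± 826 to 21840 ± 728. CDKN1C, the p57 inhibitor, rose 4.03-fold, and the transcription factor MEF2C 2.37-fold (log2 1.24 ± 0.34). Leaving out myotube array 2 ended the calls of CDKN1C (limma adjusted p = 0.0529) and MEF2C, and MEF2C was also lost without myotube array 3 or myoblast array 2 or 3 (adjusted p up to 0.144). Neither was called with the series as a block (log2 1.06, adjusted p = 0.0736, and 1.33, adjusted p = 0.182). Adjusted over the list alone 4 rose and 1 fell. The fusion peptide gene MYMX had a change of 1.39 ± 0.46 (limma adjusted p = 0.0746) and RB1 one of -1.10 ± 0.33 (adjusted p = 0.0539). With the series as a block these changes were 0.69 and -0.99. Values for MEF2A, TCF12, TCF3, TCF4 and SMARCD3 were 0.29 ± 0.69, -0.30 ± 0.26, -0.60 ± 0.24, 0.17 ± 0.27 and 0.54 ± 0.27, none past the threshold with all arrays and no block or covariate. Other settings called RB1 lower in 6 of 21, MYMX higher in 3 of 20, SMARCD3 higher in 1 of 22 (without myoblast array 1) and TCF3 lower in 1 of 22 (-0.83 with the spike-in covariate, limma adjusted p = 0.0417). Of 9 tested probe sets of TCF3, 1 was called lower. MYOD1, MYF5, MYOG and MYF6 lay below the filter on dim probe sets: MYOG gave signals of 184, 112 and 117 in myoblasts and 325, 333 and 248 in myotubes.

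Of 40 genes of the G2 and M phases 29 fell and 11 did not pass (median -1.57, camera adjusted p = 2.11e-20, and adjusted p = 0.0356 with an estimated correlation). PRC1 went from 3822 ± 167 to 156 ± 115, CDC20 from 3898 ± 700 to 202 ± 201, and the spindle checkpoint gene MAD2L1 fell 6.63-fold. Of 36 genes of the G1 and S phases 17 fell and 19 did not pass (median -0.89, adjusted p = 2.11e-11, and adjusted p = 0.0344 with an estimated correlation), among them RRM2, which went from 12030 ± 1463 to 1518 ± 330, and the replication helicase genes MCM2 and MCM5, 4.40-fold and 4.08-fold lower (at least 3.10-fold and 2.13-fold by the bound above). Of 18 histone and chromatin genes 11 fell and 1 rose (median -1.51, adjusted p = 2.72e-10, and adjusted p = 0.0666 with an estimated correlation). HMGB2 fell 9.78-fold and the lamin LMNB1 5.75-fold, and the linker histone H1-2 rose 2.80-fold, a call lost without myotube array 2 (limma adjusted p = 0.0741). Adjusted over the list alone the falls numbered 33, 20 and 13. With the series as a block 14, 7 and 8 genes fell, the medians were -1.42, -0.92 and -1.50, and the lists were called, though not with an estimated correlation (adjusted p = 0.0547, 0.0547 and 0.0813). That fit ended the calls of MAD2L1, MCM2, MCM5, LMNB1 and H1-2 (log2 -1.83, -1.70, -1.79, -1.94 and 1.15, adjusted p = 0.0603, 0.142, 0.0763, 0.075 and 0.175). Among cell cycle inhibitors and p53 targets, 3 of 14 rose, CDKN1C, CDKN1A and BTG1, and the list was not called (adjusted p = 0.387). BTG1 was lost when one of 4 arrays was left out (limma adjusted p up to 0.14) and with the series block (adjusted p = 0.195).

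Of 19 ribosome biogenesis and nucleotide synthesis genes 7 fell (median -0.50, camera adjusted p = 8.25e-07, and adjusted p = 0.0356 with an estimated correlation). They included ODC1, the first enzyme of polyamine synthesis, 3.36-fold lower, the nucleolar protein gene NCL, 2.44-fold lower, and HPRT1, 2.33-fold lower. Of 20 genes of the Id, Notch and differentiation inhibitor list 6 fell and 2 rose (median -0.28, adjusted p = 0.0265, and adjusted p = 0.176 with an estimated correlation). ID1 went from 17030 ± 1037 to 1688 ± 214 and ID3 from 6962 ± 1602 to 250 ± 154, SNAI2 fell 2.22-fold, and HES1 and NOTCH3 rose 2.57-fold and 2.02-fold. Of 18 immediate early genes 6 fell and 2 rose (median -0.60, adjusted p = 0.0113, and adjusted p = 0.195 with an estimated correlation). The phosphatase gene DUSP1 fell 2.67-fold and FOSL1 2.62-fold, while KLF4 and IER3 rose 2.62-fold and 1.76-fold. Of 21 oxidative phosphorylation genes 3 fell, CYCS, ATP5PB and COX5A (median -0.25, adjusted p = 0.0265, and adjusted p = 0.388 with an estimated correlation). With the series as a block the Id and Notch list (adjusted p = 0.0868) and the immediate early list (adjusted p = 0.0583) were no longer called, nor were NCL, HPRT1, SNAI2, FOSL1, HES1, NOTCH3, KLF4, IER3, CYCS, ATP5PB and COX5A by limma (adjusted p from 0.0603 to 0.45). Of these genes HES1, KLF4, IER3 and COX5A shrank by more than 1.5 times (to log2 0.70, 0.91, 0.50 and -0.54), and the others did not, with NCL at -1.08, SNAI2 at -1.01, FOSL1 at -1.19 and NOTCH3 at 1.14. The oxidative phosphorylation list was not called after quantile normalization (camera adjusted p = 0.261), which also shrank the brightness trend given above. Its shift and that trend were not separated here. Without myotube array 2 the oxidative phosphorylation, Id and Notch, and immediate early lists had camera adjusted p-values of 0.0904, 0.0641 and 0.0732. The first was also lost without myoblast array 1 (0.0608) and the last without myoblast array 2 (0.0599). In all, the 3 lists were called lower in 18, 17 and 17 of 22 other settings. Calls of HES1, NOTCH3, KLF4, IER3, ATP5PB and COX5A were lost when one of 4 or 5 arrays was left out, with limma adjusted p-values up to 0.159, 0.134, 0.087, 0.136, 0.076 and 0.0742. Adjusted over the list alone, 11 ribosome biogenesis genes, 6 of the Id and Notch list, 8 immediate early genes and 3 of oxidative phosphorylation fell.

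Of 39 extracellular matrix genes 18 rose and 21 did not pass (median 0.79, camera adjusted p = 2.98e-09, and adjusted p = 0.175 with an estimated correlation), among them COL3A1, which went from 11270 ± 3895 to 71240 ± 1658, POSTN, 4.29-fold higher, and LUM, 4.26-fold higher. The POSTN value was 0.79 on the log2 scale with the series as a block, against 2.10 without it. Of 10 fibroblast markers 8 rose (median 1.43, adjusted p = 1.32e-07, and adjusted p = 0.0356 with an estimated correlation). S100A4 rose 6.97-fold, LUM 4.26-fold and MFAP5 3.90-fold. DCN and LUM are members of both lists. Of 9 osteoblast and chondrocyte markers 3 rose, COL11A1, MGP and SPP1 (median 0.86, adjusted p = 0.00399, and adjusted p = 0.388 with an estimated correlation), and with the series as a block that list was not called (adjusted p = 0.0583). Of 17 interferon response genes 10 rose (median 1.05, camera adjusted p = 2.24e-07, and adjusted p = 0.176 with an estimated correlation). Among them were IFIT1 (3.91-fold), IFITM1 (3.49-fold) and MX1 (3.49-fold). By the bound above these were at least 2.425-fold, 3.49-fold and 2.62-fold, so their order is open. With the series as a block 0 of the 17 passed by limma (11 at an unadjusted p under 0.05), while the list was called (median 0.79, adjusted p = 1.92e-06), though not with an estimated correlation (adjusted p = 0.06). No list was called with both the block and an estimated correlation, where the lowest adjusted p was 0.0547. MGP and SPP1 lost their calls with the block (log2 1.496 and 0.356, adjusted p = 0.104 and 0.456). POSTN was lost without myotube array 1 or 2, and MX1 and SPP1 without these or myoblast array 2 or 3 (SPP1 also without myotube array 3; limma adjusted p up to 0.0784, 0.101 and 0.157). Adjusted over the list alone, 27 matrix, 9 fibroblast, 3 osteoblast and chondrocyte and 14 interferon genes rose.

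Ribosomal protein genes were called higher as a list (24 genes, median 0.61, camera adjusted p = 0.000858) with 0 of 24 members past the threshold by limma, 0 adjusted over the list alone, and 4 at an unadjusted p under 0.05. The call was absent with an estimated correlation (adjusted p = 0.534), with the series as a block (median -0.04, adjusted p = 0.729), after quantile normalization (0.08, adjusted p = 0.715) and without probe sets above 40000, which left 5 genes (0.57, adjusted p = 0.19). RPL18 and RPS19 had the smallest p, with log2 changes of 0.68 ± 0.24 and 1.01 ± 0.36.

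The remaining lists were not called with all 6 arrays and no block. Smooth muscle and non-muscle cytoskeleton genes went both ways, 4 of 24 higher and 3 lower (camera adjusted p = 0.708): CNN1, ACTA2 and TAGLN, contractile genes of smooth muscle, rose 4.04-fold, 3.38-fold and 3.31-fold, and SMTN fell 2.19-fold. In the adhesion and fusion list ADAM12 and VCAM1 rose 3.01-fold and 2.81-fold and CDH2, MBNL1 and CD44 fell (camera adjusted p = 0.553, median -0.10 and mean 0.06). Of the tested probe sets, 1 of 3 was called for ADAM12, 1 of 2 for CDH2, 2 of 3 for MBNL1 and 1 of 7 for CD44. In IGF signalling 3 of 13 rose, the binding proteins IGFBP6, IGFBP3 and IGFBP4 (adjusted p = 0.248, and 0.0308 in the first series alone). In the unfolded protein and heat shock list 3 of 25 rose, led by DDIT3 and TRIB3, and 6 fell, led by HSPE1 (adjusted p = 0.248). With the series as a block that list was called lower (4 genes lower and 1 higher, median -0.18, adjusted p = 0.0351, and adjusted p = 0.418 with an estimated correlation). In cholesterol synthesis 1 of 14 fell, ACAT2 (adjusted p = 0.369). Among markers of other cell types, 0 of 6 macrophage and blood, 0 of 5 endothelial and 0 of 6 adipocyte genes passed by limma (2, 1 and 1 at an unadjusted p under 0.05; median changes 0.80, 0.80 and 0.34, list adjusted p = 0.16, 0.248 and 0.387). Of 8 neural and glial markers NES rose and TUBB3 fell (adjusted p = 0.0679). Without myotube array 3 the neural list (0.0427), and without myotube array 2 the macrophage list (0.0371), was called higher. Of the genes named in this paragraph, VCAM1, CDH2, MBNL1, CD44, IGFBP4, DDIT3, ACAT2, NES and TUBB3 lost their calls when 1 array was left out, in each case myotube array 2 or myoblast array 3 or both, with limma adjusted p-values up to 0.06, 0.12, 0.139, 0.108, 0.0531, 0.142, 0.126, 0.0529 and 0.173. The series block ended the calls of VCAM1, CDH2, MBNL1, CD44, IGFBP3, DDIT3, ACAT2, NES and TUBB3 (adjusted p from 0.0736 to 0.513). Of these MBNL1 and DDIT3 shrank by more than 1.5 times (to log2 -0.40 and 0.43), and the others did not, with VCAM1 at 1.53 and CDH2 at -1.78.

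**Figure D3:**
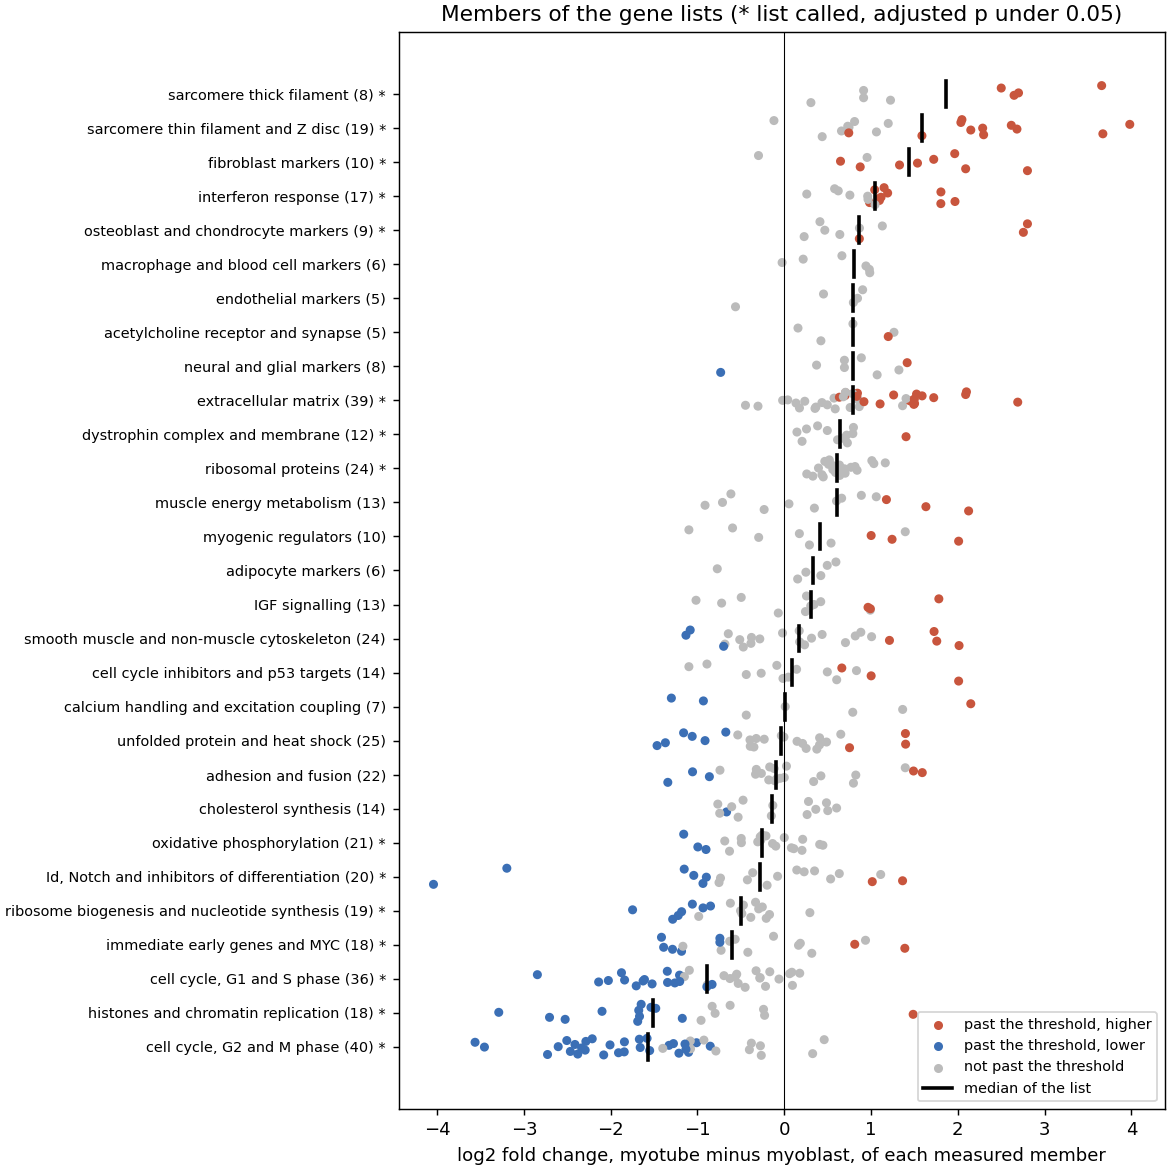
Log2 fold change, myotube minus myoblast, of each measured member of the 29 gene lists, with the number of members in parentheses and the list median as a black bar; coloured points passed the threshold and asterisks mark called lists. The median was 1.86 for thick filament genes and -1.57 for genes of the G2 and M phases.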

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

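The tests with the spike-in signal as a covariate and of fibroblast transcripts were chosen after the results were seen; the splits of the arrays were planned. Control probe sets, which the comparison did not use, carried signal. The control probe set for Alu, a repeat of primate genomes, lay at or above the 99.76th percentile of all probe sets on each array. Its signals of 52704 to 275505 exceeded every unspiked control, which argues against mouse RNA alone, although the labels give the organism as mouse. This is 1 probe set and no sequences were matched, so the species of the RNA stays open. The ribosomal RNA control probe sets differed 241.9-fold between the highest and the lowest array. Their geometric means were 699 and 249 on myoblast arrays 2 and 3, which also had the lowest spike-in signals. On the other arrays, myoblast array 1 among them, they were between 5983 and 60141.

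The first pattern is the difference between the groups as a whole. It may come in part from whatever made the spike-in level unequal, since myoblast arrays 2 and 3 had the lowest spike-in signals. With the spike-in signal as a covariate, 679 of the 1042 called genes were called in the same direction. Far fewer kept their call with the laboratory series as a block, which sets myoblast arrays 2 and 3 apart. A linear covariate on 6 arrays cannot fully separate spike-in level from group when both lowest levels are of myoblasts. The kept calls therefore do not decide whether the spike-in level is the whole cause. Of 10 splits of the 6 arrays into 3 and 3, 1 gave as many genes, the real one with 1042 genes and 1478 probe sets against a highest other value of 0 for both by limma. At an unadjusted p under 0.05 the real split gave 2606 genes and the highest other 1924. That other split set myoblast array 1 and myotube arrays 1 and 2, the 3 with the highest spike-in signals, against the rest. The next highest gave 374, so many genes at this level also follow the spike-in signal. For lists, 1 split gave as many, with 15 lists against a highest other of 11, so list calls also arise from other structure among these arrays. With 10 splits the share cannot go under 0.05. Scan day and chip lot cannot be told apart from group, and differentiation remains open.

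The second pattern is which lists depend on the spike-in level of the arrays. With the covariate the ribosomal protein median was 0.25 against 0.61 and the list was no longer called, so unequal spike-in level may be a source of that shift. For the dystrophin complex list the median was 0.35 against 0.65 with the call lost. Spike-in level and group cannot be told apart there, because most of the change remained while the call was lost. They cannot be told apart either for osteoblast and chondrocyte markers, which stayed called while the median was 0.33 against 0.86. In the Id and Notch, immediate early and oxidative phosphorylation lists members went both ways, so medians of -0.085, -0.433 and -0.253 decide nothing and the causes cannot be told apart. The first lost its call, although its ID1 and ID3 were called in all 22 settings, and the others kept theirs. For the other called lists the call at the preset correlation stayed. Other splits of the arrays also gave up to 11 such calls. A kept call therefore does not decide against the spike-in level as the whole cause. Medians with the covariate were 1.67 for thick filament, 1.17 for thin filament and Z disc, 0.61 for extracellular matrix, 0.92 for interferon response, 1.26 for fibroblast markers, -0.89 for G1 and S phase, -1.45 for G2 and M phase, -1.603 for histones and -0.72 for ribosome biogenesis. None of these calls was made with an estimated correlation in that fit.

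The third pattern is the rise of fibroblast markers with muscle genes, for which a larger share of fibroblast-like cells is a candidate explanation. In the fit with the laboratory series as a block, the median change of 4 abundant fibroblast transcripts, COL1A1, COL1A2, FN1 and COL6A3, was 0.079 against 1.13 for the marker list. That fit rests on 1 myoblast array, and without the block the medians were 1.38 and 1.43, with COL1A1 alone of the 4 past the threshold. The fits differ, so the share and a change within the muscle cells cannot be told apart.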

How the results depend on the processing

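The laboratory series, averaged myoblast arrays, spike-in covariate and bright probe set settings were chosen after seeing the data. Of 1042 called genes 222 kept their call with the series as a block, and all kept their direction. That fit compares myoblast array 1 with the myotube arrays, so for the 1034 whose groups do not overlap the direction was fixed in advance. Probe sets past the threshold numbered 1478 in the report, 908 without the trend, 400 with chip lot as a random block, 330 with the series as a block, 174 in the first series alone and 577 with myoblast arrays 2 and 3 averaged; leaving out 1 array gave 488 to 3454. Genes numbered 1042 in the report and, in the same settings, 317 with chip lot, 263 with the series block, 136 in the first series alone and 402 with the average; leaving out 1 array gave 393 to 2304. The replicate number as a block gave 2316 probe sets and 1631 genes. Arrays of the same number had deviations correlating at 0.245, -0.18 and 0.379. Myoblast array 2 and myotube array 3, of unlike numbers, reached 0.41. The check therefore does not show that the numbers pair the arrays, and with so few arrays it does not exclude it. By fry, which does not compare a list with other genes, 17 lists moved one way. Lists called numbered 15 in the report and 4 with an estimated correlation; the other settings gave 11 to 16, and leaving out 1 array 13 to 16. The share of called genes that were higher was 46.4%, and 57.0% with the series block. The fewer samples account for part of the lower counts when arrays are left out or averaged; otherwise the cause was not tested.

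Values that turned in sign were, for MEF2A, -0.467 without myoblast array 1 and -0.276 without myotube array 3 (leaving out 1 array, -0.467 to 0.868); for TCF12, 0.133 with the series block, 0.133 in the first series alone and 0.069 with the spike-in covariate; for TCF4, -0.089 with the mean of its probe sets and -0.031 without myoblast array 1 (-0.031 to 0.286). TCF3 gave 1.971 with the larger pseudocount, 2.239 after quantile normalization, 0.008 with the mean of its probe sets, 2.109 and 1.385 without myoblast arrays 2 and 3, 0.103 in the first series alone and 1.839 with the average (leaving out 1 array, -0.641 to 2.109). NASP gave 0.525 with a pseudocount of 1, 0.244 after quantile normalization, 0.658, 0.334 and 0.318 without myoblast arrays 1, 2 and 3, and 0.326 with the average (leaving out 1 array, -3.035 to 0.658). For TCF3 and NASP another probe set was the brightest in these settings, apart from 2 kinds. With the mean of probe sets, where TCF3 turned, probe sets were averaged. With the averaged myoblast arrays the probe set used was not checked. For lists, the direction of the test turned, which can differ from the sign of the median. For the calcium handling list, never called, it turned from lower to higher in settings with medians of 0.234 without a filter, -0.029 after 75th percentile scaling, 0.429 with the mean of probe sets, 0.3 and 0.106 without myotube arrays 1 and 3 and -0.07 with the series block (main median 0.011; leaving out 1 array, -0.466 to 0.3). The cytoskeleton list turned at -0.196 after quantile normalization and -0.151 without bright probe sets, ribosomal proteins at -0.045 with the series block and -0.045 in the first series alone, and cholesterol synthesis at 0.002 in the first series alone (its median was also above 0, with the test still lower, without myoblast array 1, 2 or 3, at 0.019, 0.058 and 0.041, and with the average, at 0.049); the cause was not tested. Of 89 named genes past the threshold, 54 were called in each fit with 1 array left out that gave a value (51 had a value in all of them) and 33 in every setting that gave a value. Signal near that of unspiked controls limits MYOD1, MYF5, MYOG and MYF6.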

Other observations

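The scan of gene families was chosen after the data were seen. Of 126 families of tested genes sharing a symbol stem, with at least 8 members each, 6 were called higher and 14 lower by camera, and 0 with an estimated correlation. Metallothioneins, small metal-binding proteins, had the smallest adjusted p (9.08e-05, and adjusted p = 0.739 with an estimated correlation). Of 8 members 5 fell by limma: MT1F, MT1E, MT1X, MT1G and MT1H, with log2 changes of -3.08 ± 0.38, -2.19 ± 0.37, -2.19 ± 0.39, -1.95 ± 0.30 and -1.93 ± 0.53. The family median was -1.94, and -2.28 after quantile normalization, -1.99 after 75th percentile scaling and -2.98 with the laboratory series as a block. These genes are close copies, so their probe sets can share transcripts.

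Of 8 genes of the CCT chaperonin, which folds actin and tubulin, 5 fell, with a median of -0.68 (adjusted p = 0.00179, and adjusted p = 0.655 with an estimated correlation). Of 30 MRPL genes of the large mitochondrial ribosome subunit 8 fell, with a median of -0.41 (adjusted p = 0.000749, and adjusted p = 0.655 with an estimated correlation). Of 14 genes with HLA symbols, most of antigen presentation but with an antisense transcript and pseudogenes among them, 6 rose, with a median of 0.93 (adjusted p = 0.00233, and adjusted p = 0.739 with an estimated correlation). Both scalings kept the direction of all 3 families. With the laboratory series as a block the medians were -0.75, -0.42 and 0.44 (adjusted p = 0.00125, 0.00342 and 0.0275).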
